A study of Homo sapiens with 16 samples.

How the data were processed

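Gene expression was measured in HMEC-1, an established line of human dermal microvascular endothelial cells, kept in medium with little serum from the day before treatment, per the labels. Total RNA was amplified, biotinylated and hybridised to Illumina BeadChips, on which each probe is carried by many beads. The 4 groups were untreated cells, cells given interferon gamma (IFN-γ, 1 ng/ml) for 3 h, cells given interleukin 6 (IL-6, 50 U/ml) for 1 h, and cells given IFN-γ for 2 h and then IL-6 for 1 h. For IFN-γ alone the treatment protocol gives 3 h and the sample titles give 2 h followed by 1 h at an IL-6 dose of 0, and the 1 h for IL-6 alone is given by the titles only. The labels do not say whether IFN-γ stayed in the medium during the last hour, and the extraction protocol speaks of monocytes where the sample labels name HMEC-1. Each group held 4 arrays, the labels gave 4 separate experiments with every group in each, and experiments 1 and 2 lay on slide 1 and experiments 3 and 4 on slide 2.

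The deposited table gave the intensity of 22184 probes on 16 arrays on a linear scale, neither background corrected nor normalized between arrays. BeadStudio is named in the submitters' processing notes, with no role or version. Set against the deposited intensity of single beads, 87.94% of the table's values equalled, within a relative tolerance of 1e-05, the mean of a bead type after beads beyond 3 unscaled median absolute deviations were left out. All 22184 probes could be paired with a bead code in this way. The deposited series matrix held log2 values taken as quantile normalized by the authors. The order of probes on each array was unchanged (Spearman's rho 1.0), and the median was 6.77 on every array. Equal medians alone do not show which normalization was used. The matrix was used as an alternative only, and no value column was left without a sample.

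The plan made before the data were examined assumed detection p-values or control probes, and the table gave presence and absence letters instead. Those letters were not used, because on each array between 1850 and 2726 probes called present were dimmer than the dimmest probe called absent. Instead, 755 bead codes without a probe were taken as background. They carry no label, and 8 of them were above 3 times their own median of 73.11. The values were corrected by normexp with robust background estimates from these codes (offset 16), put on the log2 scale and quantile normalized with limma's neqc. A probe's detection p was the share of background codes at least as bright on that array, and a probe was kept with a detection p under 0.05 on at least 4 of 16 arrays. Of the probes, 19715 had 1 gene symbol, 0 had several and 2469 had none listed, and 12956 were detected, 1196 of them without a listed gene. Symbols were looked up by gene ID for 19695 probes and 0 changed. For each gene the detected probe with the highest mean was used, which mattered for 1053 genes and gave 10502 genes. The probes of LIPT1 and TAP2 with values of 9 to 10.4 on slide 2, against 168.3 to 445.3 on slide 1, were left out as unusable, and TAP2 was measured by its other probe. Some genes fixed beforehand were not tested, for want of a listed or a detected probe.

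Depth on an array is signal over background. The 95th percentile of probe intensity was 27.0 to 42.4 times the background median, and the median number of beads per probe was 38 to 41. The untreated array of experiment 3 was the dimmest, with a background median of 49.5 where the other arrays had 71.0 to 79.7. A gene above background on no array of a group has only a bound there. Its change is given as at least N-fold, the bright group's mean against the dim group's mean of the higher of the dimmest detected probe and the gene's own value on each array. For a gene above background on some arrays of a group, the same floor was tried for the other arrays of that group and is given beside the changes it moved most, and with 1 array above background the change is also given as at least N-fold.

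Linear models were fitted with limma to 4 group means over all 16 arrays (12 residual degrees of freedom), with empirical Bayes moderation and Benjamini-Hochberg adjustment per comparison at 0.05 and no minimum fold. The comparisons were IFN-γ, IL-6 and the sequence of both against untreated cells, the sequence against IFN-γ alone and against IL-6 alone, and the interaction, the IL-6 change after IFN-γ minus that without it. The 24 gene lists were fixed before the data were examined: IRF and JAK-STAT transcription factors, guanylate-binding proteins, MHC class I antigen processing, MHC class II, chemokines, antiviral genes, JAK-STAT inhibitors, IL-6/STAT3 targets, cytokine receptors and kinases, endothelial adhesion and haemostasis, NF-κB targets, immediate early genes, cell death, tryptophan and redox metabolism, immune checkpoint, cell cycle, cholesterol biosynthesis, stress response, housekeeping, and markers of endothelial cells, monocytes, lymphocytes, fibroblasts and smooth muscle, and epithelium. They were tested with camera at a preset inter-gene correlation of 0.01 and with an estimated correlation, adjusted over the 23 lists with at least 3 measured genes. Fry, a test of a list on its own, was adjusted in the same way. It is given where a list that passed with the estimated correlation did not pass with fry. The responsive sets were chosen on the mean IFN-γ or mean IL-6 effect over both levels of the other cytokine. In this balanced design that effect is independent of the interaction only where all groups vary equally. The sets were tested by an exact two-sided sign-flip test over the 4 experiments, whose smallest p is 2 in 16.

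Genes were named by a rule fixed beforehand: per comparison the 10 largest increases and the 10 largest decreases among genes past 0.05 that moved the same way in all 4 experiments, or, with none, the 3 smallest p-values; 18 genes of interest where tested; and up to 4 members of each list by p-value. Genes named outside this rule are said to be chosen after their values were seen. The experiment number pairs the arrays, since the labels give it as a shared experiment: over 24 pairs of arrays of an experiment the deviations from the group means correlated with a median of 0.492 (lowest -0.279, 21 pairs above 0.1), against a median of -0.164 between experiments. The fit without this block was the planned one, and the fit with it was an alternative.

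The model was tested on simulated data with 200 genes changed. Values were drawn independently for each gene and array, with 1 spread per gene and no effect shared by an experiment. The real arrays pair by experiment, so the rates below are not error rates of the real fit. For IFN-γ against untreated cells it recovered 32.8%, 88.1% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale, with 7 false calls among 154. For IL-6 against untreated cells it recovered 38.8%, 76.1% and 97%, with 5 false calls among 146. Alternatives changed the background correction, the normalization, the detection filter, the choice of probes, the blocks, the arrays in the fit, the variance model, the array weights and the source of the values, and left out each experiment and each array. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.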

Results

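Expression of 10502 genes was measured in HMEC-1, a line of human microvascular endothelial cells, in 4 groups of 4 arrays. Cells were untreated, given IFN-γ for 3 h, given IL-6 for 1 h, or given IFN-γ for 2 h and then IL-6 for 1 h. The 3 h are those of the treatment protocol, and the titles of the same arrays give 2 h of IFN-γ and then 1 h at an IL-6 dose of 0. IFN-γ is the type II interferon, which signals through the kinases JAK1 and JAK2, and IL-6 signals through the receptor chain IL6ST and the transcription factor STAT3. The labels give 4 separate experiments, each with all 4 groups, on 2 slides of 2 experiments each. The 95th percentile of probe intensity was 27.0 to 42.4 times the background of its array, and the number of arrays limits the precision. The first principal component held 51.2% of the variance. It was low on the untreated and IL-6 arrays of experiments 1 and 3 and on the IFN-γ array of experiment 1, and its group means were -14.6 in untreated cells, -5.8 with IL-6, 7.4 with IFN-γ and 13 with both.

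The comparison of IFN-γ with untreated cells asked what this cytokine alone changed. The largest rises were in chemokines, GTPases and transcription factors of the interferon response. CXCL10, a chemokine that attracts T cells, was 30.3-fold higher (log2 change 4.92, SE 0.26, n = 4 per group). CXCL11, which binds the same receptor, was not above background in untreated cells and was at least 17.0-fold higher with IFN-γ. CCL8, a monocyte attractant, and the transcription factor BATF2 were above background on 1 of 4 untreated arrays and were at least 12.7-fold and 7.85-fold higher. The transcription factors IRF8 and IRF1 rose 16-fold and 10.4-fold, and the guanylate-binding GTPases GBP4 and GBP1 rose 14.1-fold and 12-fold. SOCS1, a feedback inhibitor of JAK kinases, was at least 10.7-fold higher, and HAPLN3, a link protein of the hyaluronan matrix, at least 11.6-fold higher. Each of these 10 genes was higher in 4 of 4 experiments, with limma adjusted p-values between 1.18e-14 and 2.84e-08.

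Decreases were smaller. PPP1R3C, a subunit that directs protein phosphatase 1 to glycogen, fell by 1.07 on the log2 scale (SE 0.14, adjusted p = 9.74e-05). The mTORC1 inhibitors DDIT4L and DDIT4 fell by 0.96 and 0.89, the growth factor HBEGF by 0.89, and the Hedgehog receptor PTCH1 by 0.77 (0.66 with the IFN-γ arrays not above background at the floor). The Notch-modifying enzyme LFNG fell by 0.81 (0.74 likewise), the BH3-only gene BMF by 0.76, MEDAG by 0.75, the adaptor SH2D3C by 0.75 and the chemokine receptor CXCR4 by 0.72, each of the 10 in 4 of 4 experiments. The calls of LFNG and BMF rested on single arrays. LFNG's was lost without any of the IFN-γ and untreated arrays but untreated replicate 3, BMF's without any but IFN-γ replicate 2 and untreated replicate 1, and MEDAG's without IFN-γ replicate 2 or experiment 3 or 4, with changes that stayed between -0.97 and -0.60, between -0.89 and -0.65 and between -0.87 and -0.65. Of the calls that held without each single array, those of CXCR4 and SH2D3C were lost without experiment 2 or 4 (changes up to -0.64 and -0.59) and that of PTCH1 without experiment 2 or 3 (up to -0.65).

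In all, limma called 233 genes higher and 40 lower, 113 of them higher by more than 1 on the log2 scale and 1 lower by as much, and 272 of the 273 moved the same way in 4 of 4 experiments. Median centring in place of quantile normalization called 237 higher and 16 lower, 14 of these among the 40. With slide as a block the counts were 250 and 53, and within slide 1 and slide 2, with 2 experiments each, 64 and 2 and 113 and 4. All 57 named genes called here had the same sign on both slides. For the largest changes the naming rule fixed this, since it asks for the same direction in 4 of 4 experiments. With the experiment as a block 353 genes were higher and 144 lower, among them all 233 and all 40. Without experiment 4 the counts were 140 and 10. Without experiment 2 or experiment 3 only 16 genes were lower, and without IFN-γ replicate 2, 3 or 4 the lower genes numbered 25, 21 and 19. In experiments 2 and 4 alone, away from most arrays low on the first component, 19 genes were lower, 11 of them among the 40. Strict detection, with fewer genes tested, lowered both counts and array weights raised both, by amounts given with the alternatives below. Fitting only the groups compared lowered the count of lower genes.

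Of 12 measured IRF and JAK-STAT transcription factors 10 rose, 11 adjusted over the list alone, with a median log2 change of 1.46 (1.41 on slide 1 and 1.51 on slide 2, 1.38 with CIITA at its bound; camera adjusted p = 8.71e-43). NLRC5, the activator of MHC class I genes, rose by 1.82 (SE 0.10), and CIITA, the activator of MHC class II genes, was at least 1.69-fold higher. STAT3 rose by 0.64 (adjusted p = 0.027), a call lost without experiments 2, 3 or 4 and without any of IFN-γ replicates 2, 3 and 4 and untreated replicates 1 and 4, with changes from 0.50 to 0.74. All 5 guanylate-binding proteins rose, 5 adjusted over the list alone, with a median of 3.16 (3.19 and 3.13 on the slides, 2.78 with GBP5 at its bound of at least 4.87-fold; adjusted p = 2.63e-26). Of 31 antiviral genes 22 rose, 27 adjusted over the list alone, with a median of 1.16 (1.04 and 1.21 on the slides; adjusted p = 2.3e-55). Among these, IFIT3 and IFIT2 rose by 2.52 and 2.10, the RNA sensor RIGI by 1.42 and the ADP-ribosyltransferase PARP9 by 1.78.

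Of 17 genes of MHC class I antigen processing 5 rose, 7 adjusted over the list alone, with a median of 0.39 (0.13 and 0.58 on the slides; adjusted p = 4.7e-12). Experiment 3, whose untreated array was the dimmest, carried much of this median and of the difference between slides: the experiments had 0.23, 0.18, 0.79 and 0.19, and the median was 0.22 without experiment 3, where the list still passed. The peptide transporter genes TAP1 and TAP2 rose by 2.17 (SE 0.11) and 1.05, HLA-E by 0.84 and the peptidase ERAP2 by 0.64, the last not called without experiment 4 (adjusted p = 0.103). Of 4 measured MHC class II genes 2 rose, 2 adjusted over the list alone: the lysosomal protease CTSS, at least 2-fold higher, and HLA-DOB, at least 1.97-fold higher, each above background on 1 of 4 untreated arrays, with a list median of 0.75 (0.66 and 0.80 on the slides; adjusted p = 4.4e-06). Of 13 list members 12 were on the array. HLA-DRA, HLA-DRB1, HLA-DRB5, HLA-DPA1, HLA-DPB1 and HLA-DQB1 were among those above background on too few arrays to be tested. The median therefore describes CTSS, HLA-DOB, CD74 and HLA-DMA only. CD74, the invariant chain, had a change of 0.35 (SE 0.25), or 0.11 with the 2 untreated arrays not above background at the floor. Of 12 chemokines 7 rose, 7 higher and 1 lower (CXCL8, -0.66, chosen after its value was seen) adjusted over the list alone, with a median of 0.97 (0.76 and 1.15 on the slides, 0.58 with 3 genes at their bounds; adjusted p = 4.93e-17). CXCL9 was at least 4.26-fold higher.

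In the cell death list 6 of 14 genes rose, 8 adjusted over the list alone, with a median of 0.45 (0.32 and 0.64 on the slides, 0.43 with a gene at its bound; adjusted p = 1.45e-13). Experiment 3 again stood apart, with 0.97 where experiments 1, 2 and 4 had 0.37, 0.34 and 0.38, and without it the median was 0.32 and the list still passed. They included the apolipoproteins APOL6, APOL2 and APOL3, by 2.33, 2.23 and 2.16, and the death ligand TNFSF10, by 2.13 (SE 0.26). Of 6 genes of tryptophan and redox metabolism 4 rose, 4 adjusted over the list alone, with a median of 0.83 (0.78 and 0.77 on the slides, 0.59 with IDO1 at its bound; adjusted p = 4.7e-12). WARS1, the tryptophan tRNA synthetase, rose by 3.16 (SE 0.14), the methyltransferase NNMT by 0.98, GCH1, of tetrahydrobiopterin synthesis, by 0.70, and IDO1, which degrades tryptophan, was at least 1.39-fold higher. In the immune checkpoint list 1 of 5 genes rose, 1 adjusted over the list alone: CD274, which encodes PD-L1, by 1.30 (SE 0.25, or 1.22 with the untreated arrays not above background at the floor), not called without experiment 4 (lowest change of the leave-outs 1.07, highest adjusted p 0.0989). The list's median was 0.09 (0.10 and 0.24 on the slides; adjusted p = 0.0113), or 0.17, 0.18 and 0.17 without experiments 2, 3 and 4.

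IL-6/STAT3 targets had a median of 0.26 (0.37 and 0.39 on the slides; adjusted p = 1.34e-07), with 6 of 18 risen, 8 higher and 1 lower (MYC, -0.46, chosen after its value was seen) adjusted over the list alone. The repressor BCL6 rose by 1.83 (SE 0.11), CEBPD by 1.06 (adjusted p = 0.0117), CEBPB by 0.92 and the IκB family member BCL3 by 1.07 (adjusted p = 0.0328). CEBPD was not called without experiment 3 or 4 or IFN-γ replicate 2 or 3 (changes down to 0.78). BCL3 was not called without experiments 1, 3 or 4, IFN-γ replicates 2, 3 or 4 or untreated replicates 1, 3 or 4 (changes 0.80 to 1.32). Of 21 immediate early genes 4 rose and 1 fell, 5 and 4 adjusted over the list alone, with a median of 0.11 (0.05 and 0.06 on the slides, 0.05 and 0.07 without experiments 1 and 2; adjusted p = 0.0113). This list's adjusted p = 0.288 with an estimated correlation, and the call was lost without experiment 4 or untreated replicate 4 (highest adjusted p 0.0704). KLF4 rose by 2.46 (SE 0.13), ATF3 by 1.69, ZFP36 by 0.81 and KLF6 by 0.55, and IER3, chosen after its value was seen, fell by 0.61. The call of ZFP36 was lost without experiment 3 or 4 and that of KLF6 without experiment 3, with changes of at least 0.69 and 0.45.

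The remaining lists did not pass. JAK-STAT inhibitors had 1 of 14 genes risen (SOCS1), 2 adjusted over the list alone, a median of -0.08 and a mean of 0.27 with a test direction upward (adjusted p = 0.352). SOCS3 was 0.93 higher (SE 0.24, adjusted p = 0.0525, and 0.0136 with the experiment as a block). In the list of cytokine receptors and kinases 1 of 9 rose, IFNAR2 by 0.62 (not called without experiment 3), 2 adjusted over the list alone (median -0.15, adjusted p = 0.459). IFNGR1 and IFNGR2, the IFN-γ receptor chains, had changes of -0.15 and 0.06, and IL6R and IL6ST of -0.17 and -0.41. The kinase JAK2 had 0.59, the PD-1 ligand PDCD1LG2 0.65 and EDN1, which encodes endothelin 1, -0.60, with adjusted p-values of 0.347, 0.382 and 0.232 in limma and 0.0169, 0.00306 and 0.000243 once the experiment was a block. Of 11 genes of endothelial adhesion and haemostasis 1 rose, the leukocyte adhesion molecule ICAM1, by 2.20 (SE 0.23), 1 adjusted over the list alone (median 0.04, adjusted p = 0.217). Of 14 NF-κB targets 2 rose, SOD2 by 1.12 (not called without experiment 4) and TNFAIP2 by 0.98, 2 adjusted over the list alone (median 0.05, adjusted p = 0.27). The cell cycle list had 0 of 24 genes called in limma and 0 adjusted over the list alone, a median of -0.12 and adjusted p = 0.082, or 0.0325 with the experiment as a block, with adjusted p = 0.35 in that fit with an estimated correlation.

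No gene was called in the lists of cholesterol biosynthesis (median of 11 genes -0.14, adjusted p = 0.494), stress response (14 genes, -0.03, adjusted p = 0.803) and housekeeping (8 genes, -0.06, adjusted p = 0.921), where GAPDH and ACTB had changes of 0.09 and -0.09. The 13 endothelial markers had a median of -0.17 (adjusted p = 0.221), with 0 called and 1 adjusted over the list alone, KDR, the VEGF receptor, at 0.55 (adjusted p = 0.0745, and 0.0225 with the experiment as a block), or 0.43 with the 2 untreated arrays not above background at the floor. All 14 monocyte markers were on the array, and 4 were above background on enough arrays to be tested, against 13 of 15 endothelial markers. These values argue against monocytes as the main cells of the samples. Monocyte markers had a median of 0.21 over 4 genes (adjusted p = 0.195), fibroblast and smooth muscle markers of 0.04 over 6 (adjusted p = 0.771) and epithelial markers of 0.01 over 3 (adjusted p = 0.744). GZMB, the measured lymphocyte marker, had a change of 0.14. Of 23 lists tested 11 passed, and all but the immediate early list also passed with an estimated correlation. The same 11 passed with slide as a block.

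**Figure D1:**
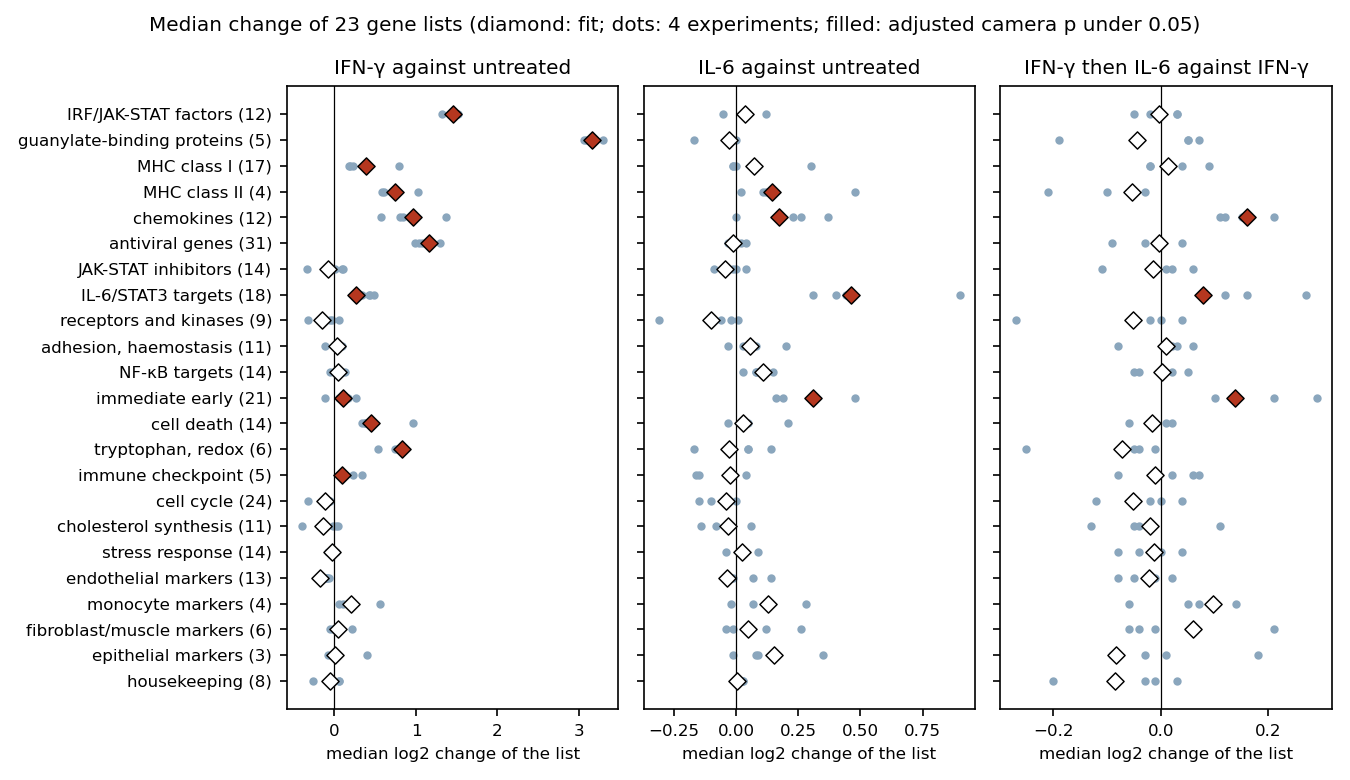
Median log2 change of 23 gene lists (number of measured genes in parentheses) for 3 comparisons, with diamonds for the fit over all arrays, dots for the 4 experiments, and filled diamonds where the adjusted camera p is under 0.05. With IFN-γ the guanylate-binding proteins stand at 3.16, and with IL-6 the STAT3 targets stand at 0.46 without IFN-γ and 0.08 after it.

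The comparison of IL-6 with untreated cells asked what 1 h of IL-6 changed without IFN-γ. SOCS3, the feedback inhibitor of the IL-6 receptor complex, rose 5.91-fold (log2 change 2.56, SE 0.24, n = 4 per group, limma adjusted p = 0.000114). CEBPD, a transcription factor of the acute phase response, rose 3.10-fold, and ID1, an inhibitor of helix-loop-helix factors, 2.75-fold. C2CD4B rose 2.70-fold, BCL3 2.65-fold and the monocyte chemokine CCL2 2.40-fold. ZFP36, which promotes decay of cytokine mRNAs, rose 2.22-fold, the repressor SNAI1 2.07-fold, the kinase MAP3K8 1.98-fold, MYC 1.96-fold and BCL6 1.80-fold. The kinase PIM1 and PLEKHF1, chosen after their values were seen, rose by 0.93 and 0.78. These 13 genes, each higher in 4 of 4 experiments, were all that limma called, with 0 lower and 115 past an unadjusted p of 0.05.

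With slide as a block 15 genes were higher and 0 lower, within slide 1 only SOCS3 was called (2.95 there and 2.17 on slide 2), and within slide 2 no gene was. No gene was higher past 0.05 when only the arrays of the groups compared were fitted, or in experiments 2 and 4 alone. With the experiment as a block 27 genes were called, among them all 13. The others included the chemokine CXCL2, at least 1.57-fold higher (adjusted p = 0.0643, and 0.00492 with the block), SOCS1, at least 1.48-fold higher (0.226 and 0.0132), FOS at 1.11 (0.763 and 0.0271), IL6 itself at 0.87 (0.112 and 0.0336) and IRF1 at 0.54 (0.207 and 0.046), and, chosen after its value was seen, SPRY1 at 0.86 (0.567 and 0.000954). The count depended on single experiments: 4 genes were called without experiment 1 (BCL6, ZFP36, SOCS3 and CXCL2), 4 without experiment 2 (CEBPD, C2CD4B, SOCS3 and BCL3), 2 without experiment 3 (CCL2 and SOCS3) and 6 without experiment 4 (CCL2, PIM1, MYC, C2CD4B, ID1 and SOCS3). Without single arrays, BCL3 lost its call in 7 cases, all but untreated replicate 2, SNAI1 in 5 (IL-6 replicates 2, 3 and 4, untreated replicates 1 and 3) and MAP3K8 in 4 (IL-6 replicates 1 and 3, untreated replicates 2 and 4), with changes of at least 1.21, 0.93 and 0.86.

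Of 18 IL-6/STAT3 targets 6 rose, 12 adjusted over the list alone, and 14 had positive changes, with a median of 0.46 (0.40 on slide 1 and 0.56 on slide 2; camera adjusted p = 4.92e-34). Of 21 immediate early genes, the fast transcription factor genes of growth signals, 2 rose (ZFP36 and MYC), 9 adjusted over the list alone, and 20 had positive changes, with a median of 0.31 (0.29 and 0.35; adjusted p = 5.99e-24). Of 12 chemokines CCL2 rose, 3 adjusted over the list alone, with a median of 0.17 (0.09 and 0.28; adjusted p = 1.58e-10). MHC class II genes had 0 of 4 called in limma, 1 adjusted over the list alone (CTSS, at least 1.17-fold higher), and a median of 0.15 (0.10 and 0.33; adjusted p = 0.0186), where adjusted p = 0.182 with an estimated correlation. That call was lost without experiments 2, 3 or 4 and without untreated or IL-6 replicates 2 or 3, with medians from 0.06 to 0.31. NF-κB targets had a median of 0.11 (0.10 and 0.05), adjusted p = 0.0612, or 0.0236 with the experiment and 0.0324 with slide as a block, and adjusted p = 0.0715 with an estimated correlation in the former.

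The lists of IRF and JAK-STAT factors, guanylate-binding proteins and antiviral genes did not pass with IL-6. The IRF and JAK-STAT transcription factors had a median of 0.04 (adjusted p = 0.0705), the guanylate-binding proteins -0.03 (adjusted p = 0.76) and the antiviral genes -0.01 (adjusted p = 0.959). GBP1 and CXCL10 had changes of -0.03 and -0.01, and ICAM1 and STAT3 of 0.18 and 0.07. The monocyte markers had a median of 0.13 (0.03 on slide 1 and 0.30 on slide 2; adjusted p = 0.117). Of 23 lists 4 passed, and all but MHC class II also passed with an estimated correlation.

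**Figure D2:**
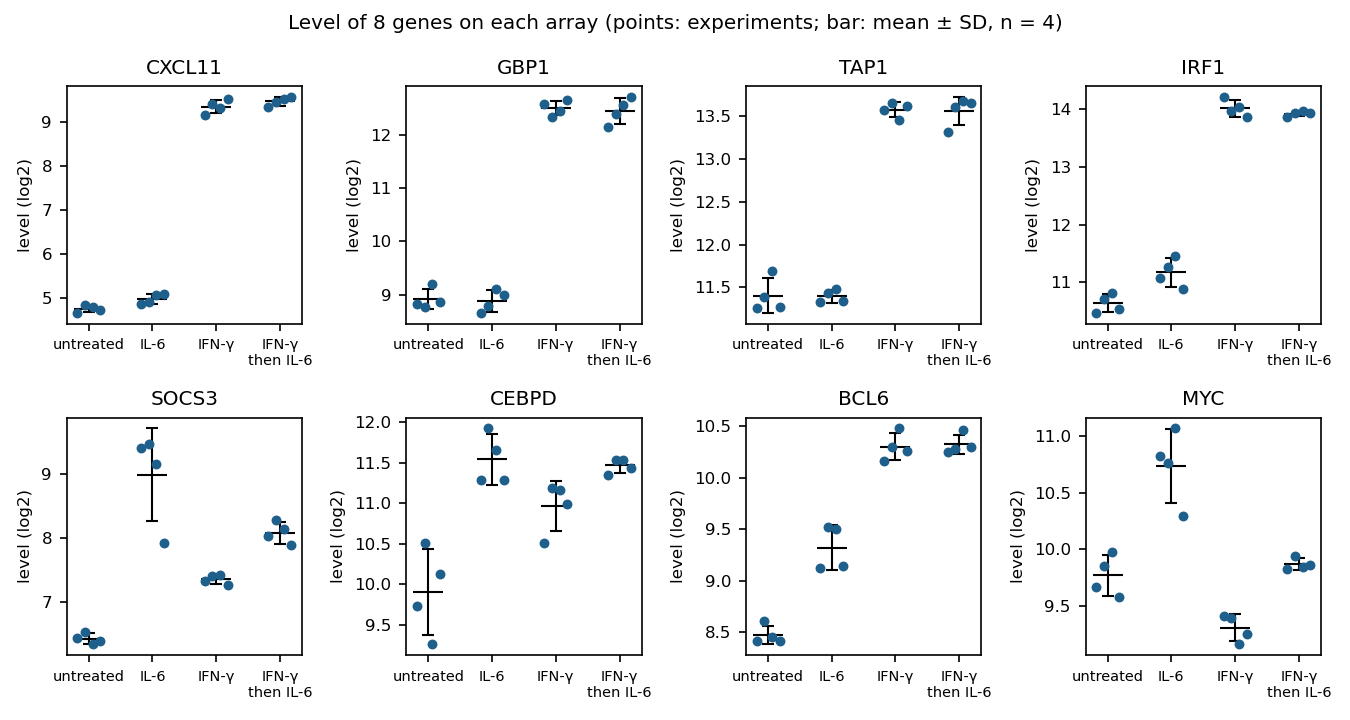
Normalized log2 level of 8 genes on each array, with points for the 4 experiments and bars for the mean and SD of each group (n = 4). CXCL11, GBP1, TAP1 and IRF1 are high in both groups with IFN-γ, while SOCS3 is highest with IL-6 alone.

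The sequence of IFN-γ and IL-6 was set against untreated cells to show the change with both. Here too the interferon-linked genes had the largest values. CXCL10 rose by 4.93 on the log2 scale (SE 0.26, n = 4 per group), IRF8 by 3.88, GBP4 by 3.78, GBP1 by 3.53 and IRF1 by 3.29. CXCL11, CCL8, SOCS1, HAPLN3 and BATF2 were at least 18.5-fold, 17.2-fold, 11.8-fold, 11.3-fold and 8.04-fold higher. Among genes of the IL-6 response SOCS3 rose by 1.65 (SE 0.24), BCL3 by 1.60 and CEBPD by 1.56. PPP1R3C fell by 1.26 (SE 0.14), DDIT4L by 1.04, DDIT4 by 1.03 and HBEGF by 0.87. SOX17, an endothelial transcription factor, and PTCH1 were at least 1.58-fold and 1.67-fold lower. FRMD6, EPHA2, MEF2D and LFNG fell by 0.86, 0.85, 0.84 and 0.80, the last 1.66-fold with the array not above background at the floor. Their calls were each lost without 4 to 7 single arrays, among them replicates 1, 2 and 3 given both cytokines and untreated replicate 1, with changes from -1.01 to -0.60.

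In this comparison limma called 239 genes higher and 53 lower, all 292 the same way in 4 of 4 experiments. Median centring called 251 higher and 24 lower. With slide as a block the counts were 257 and 64, within slide 1 they were 66 and 1 and within slide 2 125 and 6. All 58 named called genes had the same sign on both slides, which the naming rule fixed for the largest changes. The fit with the experiment as a block gave 366 and 244, among them all 239 and all 53. Without the block, leaving out experiment 4 gave 147 and 9, and without experiments 1, 2 or 3 the lower genes numbered 34, 28 and 17. Leaving out replicates 1 to 4 given both cytokines left 30, 32, 23 and 25 lower genes, and leaving out untreated replicate 1 or 3 left 33 and 35. STAT3 was 0.57 higher (adjusted p = 0.0547, and 0.000298 with the block) and IL6R, above background on 1 of 4 arrays with both, at least 1.26-fold lower (0.0618 and 0.0129). Also called with the block alone were IL6 at 0.61 (0.105 and 0.0367), JAK2 at 0.55 (0.327 and 0.0243), PDCD1LG2 at 0.57 (0.373 and 0.0081), the monocyte marker CD14 at 0.55 (0.223 and 0.0311) and PIAS3 at -0.43 (0.183 and 0.0408).

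Of 23 lists 12 passed, and the same 12 with slide as a block. Guanylate-binding proteins had 5 of 5 genes risen, 5 adjusted over the list alone, and a median of 3.11 (3.02 and 3.19 on the slides, 2.74 with GBP5 at its bound; adjusted p = 4.15e-21). The IRF and JAK-STAT factors had 10 of 12 genes risen, 11 adjusted over the list alone, and a median of 1.49 (1.53 and 1.51, 1.43 with CIITA at its bound; adjusted p = 1.52e-34), the antiviral genes 22 of 31, 26 adjusted over the list alone, and 1.13 (1.05 and 1.25; adjusted p = 3.7e-44), and the chemokines 7 of 12, 8 adjusted over the list alone, and 1.29 (1.26 and 1.32, 1.13 with 3 genes at their bounds; adjusted p = 3.58e-18). IL-6/STAT3 targets had 7 of 18 risen, 10 adjusted over the list alone, with a median of 0.59 (0.63 and 0.56; adjusted p = 1.74e-10), and immediate early genes 5 of 21 risen, 7 and 1 lower adjusted over the list alone, with 0.21 (0.26 and 0.18; adjusted p = 3.99e-07). The cell cycle list had 0 of 24 genes called in limma, 0 adjusted over the list alone, and a median of -0.17 (-0.16 and -0.19; adjusted p = 0.0276), where adjusted p = 0.31 with an estimated correlation, and the call was lost without untreated replicate 1 or replicates 3 or 4 given both cytokines (highest adjusted p = 0.0998). MHC class I processing had 5 of 17 risen, 6 adjusted over the list alone, and a median of 0.45 (0.33 and 0.57, with experiment 3 at 0.85 and the others at 0.41, 0.25 and 0.29; adjusted p = 2.04e-10), MHC class II 2 of 4, 2 adjusted over the list alone, and 0.61 (0.55 and 0.69; adjusted p = 0.000153). Cell death genes had 6 of 14 risen, 8 adjusted over the list alone, and 0.48 (0.38 and 0.63, with experiment 3 at 0.97 and the others at 0.64, 0.42 and 0.42; adjusted p = 1e-10), tryptophan and redox metabolism 4 of 6, 4 adjusted over the list alone, and 0.77 (0.76 and 0.77, 0.52 with IDO1 at its bound; adjusted p = 1.54e-08). The immune checkpoint list had 1 of 5 risen, 1 adjusted over the list alone, and a median of 0.12 (0.11 and 0.17; adjusted p = 0.0276), where adjusted p = 0.0556 with an estimated correlation, and the call was lost without experiment 4, untreated replicate 4 or replicate 1 given both cytokines (highest adjusted p = 0.101). The other 10 passed with an estimated correlation as well, immediate early genes with adjusted p = 0.0306, or 0.0761 in the fit with the experiment as a block.

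The sequence set against IFN-γ alone asked what IL-6 in the last hour changed in cells already given IFN-γ. No gene passed: limma called 0 higher and 0 lower, with 54 past an unadjusted p of 0.05 and a smallest adjusted p of 1. With the experiment as a block it also called 0 and 0, with 141 past an unadjusted p of 0.05 and a smallest adjusted p of 0.313, and it called none with slide as a block or within either slide. Of the 13 genes called with IL-6 against untreated cells, a comparison on other arrays, 12 were higher and 7 passed 0.05 adjusted over these genes alone, with the smallest values for MYC and ZFP36 (adjusted p = 0.00689 each) and ID1 (adjusted p = 0.0113). The smallest p-values belonged to MYC, ZFP36 and ABAT, the first 2 with changes of 0.56 (SE 0.14) and 0.64 (SE 0.16) and ABAT at least 1.12-fold lower, each the same way in 4 of 4 experiments. SOCS3 had a change of 0.73 (SE 0.24), BCL3 of 0.53, CEBPD of 0.50 and FOS of 0.97 (SE 0.30). CXCL10, GBP1, IRF1 and SOCS1 had changes of 0.01, -0.05, -0.10 and 0.14, and IL6R was at least 1.12-fold lower.

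As lists, 3 of 23 passed camera, also with an estimated correlation (adjusted p = 0.00662 for each). They also passed camera with the experiment and with slide as a block. With fry, which tests a list on its own, none of them passed. Its adjusted p was 0.141 for immediate early genes, 0.142 for chemokines and 0.141 for IL-6/STAT3 targets. The 21 immediate early genes had a median of 0.14 (0.16 on slide 1 and 0.17 on slide 2; adjusted p = 2.48e-16), 19 of them with positive changes, 0 called and 3 adjusted over the list alone. The 12 chemokines had 0.16 (0.29 and 0.10; adjusted p = 7.27e-09), with 0 called and 0 adjusted over the list alone. The 18 IL-6/STAT3 targets had 0.08 (0.20 and 0.11, and 0.12 without experiment 3 or 4; adjusted p = 5.71e-08), with 0 called and 3 adjusted over the list alone. The guanylate-binding proteins and antiviral genes had medians of -0.05 and 0.00 (adjusted p = 0.856 and 0.952).

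The sequence set against IL-6 alone asked what IFN-γ changed where both groups had received IL-6, and shares no array with the comparison of IFN-γ and untreated cells. CXCL10 rose by 4.94 (SE 0.26, n = 4 per group), CCL8 by 4.01, GBP4 by 3.83, IRF8 by 3.79, GBP1 by 3.56 and IRF1 by 2.75, and CXCL11, HAPLN3, BATF2, UBD and GBP5 were at least 18.5-fold, 11.4-fold, 8.21-fold, 6.05-fold and 4.71-fold higher. UBD is a ubiquitin-like modifier. ID1 fell by 1.42 (SE 0.20), HBEGF by 1.10, SPRY1, an inhibitor of growth factor signalling, by 1.08 (not called without experiment 2 or 4, changes up to -0.95), DDIT4 by 1.02, MYC by 0.87, PPP1R3C by 0.84 and DDIT4L by 0.80, and PTCH1 was at least 1.7-fold lower. BMF and LFNG fell by 0.81 each (LFNG 1.68-fold with the array not above background at the floor), calls lost without 4 and 7 single arrays (changes from -0.93 to -0.70 and from -0.98 to -0.69), among them IL-6 replicates 2 and 4 and replicates 1 and 4 given both cytokines. SOCS3 was lower, at -0.91 (adjusted p = 0.0652, and 0.0163 with the experiment as a block). Likewise called with that block alone were STAT3 at 0.50 (0.136 and 0.00111), JAK2 at 0.69 (0.216 and 0.0061), NNMT at 0.55 (0.0839 and 0.0245), PDCD1LG2 at 0.67 (0.379 and 0.00247), EDN1 at -0.67 (0.144 and 8.03e-05), IL1B at -0.52 (0.515 and 0.00298) and SOCS2 at -0.52 (0.434 and 0.00439).

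Here limma called 204 genes higher and 42 lower, 245 of the 246 the same way in 4 of 4 experiments. With slide as a block the counts were 217 and 49, within slide 1 51 and 3, and within slide 2 101 and 4. The sign was the same on both slides for all 53 named called genes, which the naming rule fixed for the largest changes. The fit with the experiment as a block gave 298 and 144. Without the block, leaving out experiment 4 gave 122 and 13, without experiments 2 and 3 the lower genes numbered 19 and 21, without IL-6 replicate 3 24, and without replicates 1, 3 and 4 given both cytokines 26, 24 and 22. Of the 204 higher genes 195 were among the 233 of IFN-γ against untreated cells, where independent lists would share 4.53, and of the 42 lower genes 21 were among the 40, where independent lists would share 0.16. The 2 comparisons share no array but come from the same experiments, whose untreated and IL-6 arrays correlated (0.66 to 0.88), and the values for independent lists leave this out, so how much of the overlap comes from the experiments is not known.

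Of 23 lists 10 passed, also with slide as a block. The antiviral genes had 22 of 31 risen, 27 adjusted over the list alone, and a median of 1.15 (0.99 and 1.17 on the slides; adjusted p = 2.37e-63), the IRF and JAK-STAT factors 9 of 12, 12 adjusted over the list alone, and 1.43 (1.57 and 1.33, 1.36 with CIITA at its bound; adjusted p = 2.44e-47), and MHC class I processing 5 of 17, 5 adjusted over the list alone, and 0.28 (0.27 and 0.45; adjusted p = 2.44e-11). Guanylate-binding proteins had 5 of 5 risen, 5 adjusted over the list alone, and 3.13 (3.05 and 3.21, 2.73 with GBP5 at its bound; adjusted p = 5.01e-30), MHC class II 2 of 4, 2 adjusted over the list alone, and 0.35 (0.34 and 0.39; adjusted p = 0.000558), and chemokines 5 of 12, 7 and 1 lower adjusted over the list alone, and 0.61 (0.54 and 0.69; adjusted p = 1.49e-14). Cell death genes had 6 of 14 risen, 7 adjusted over the list alone, and 0.32 (0.39 and 0.35; adjusted p = 8.74e-15), tryptophan and redox metabolism 3 of 6, 4 adjusted over the list alone, and 0.63 (0.62 and 0.64, 0.48 with IDO1 at its bound; adjusted p = 2.19e-10), and the immune checkpoint list 1 of 5, 2 adjusted over the list alone, and 0.14 (0.14 and 0.14; adjusted p = 0.00884). The cell cycle list had 0 of 24 called in limma, 0 adjusted over the list alone, and a median of -0.15 (-0.11 and -0.17; adjusted p = 0.0158), where adjusted p = 0.317 with an estimated correlation, and the call was lost without experiment 3 or IL-6 replicate 1 or 3 (highest adjusted p = 0.139). The other 9 held with an estimated correlation. IL-6/STAT3 targets were not among the 10, with a median of -0.02, BCL6 risen by 1.00 and MYC fallen.

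The interaction tested whether the IL-6 change differed after IFN-γ. For single genes limma called 0 higher and 0 lower, with 61 past an unadjusted p of 0.05 and a smallest adjusted p of 0.365. With the experiment as a block it called 0 and 0, with 149 past an unadjusted p of 0.05. The smallest p-values belonged to SOCS3 (-1.84, SE 0.34), BCL6 (-0.83, SE 0.16) and PLEKHF1 (-0.79, SE 0.18), each negative in 4 of 4 experiments, with adjusted p-values of 0.0896, 0.0698 and 0.119 with the block. SOCS3 had -2.17 on slide 1 and -1.50 on slide 2, and was called without IL-6 replicate 4 (-2.19, adjusted p = 3.71e-06) and without experiment 4 (-2.15, adjusted p = 0.000456). CEBPD had an interaction of -1.13 (SE 0.32), CCL2 of -0.95, BCL3 of -0.87 and IRF1 of -0.63, while CXCL10 had 0.02 (SE 0.37). The 13 genes called with IL-6 alone had a median IL-6 change of 1.15 without IFN-γ and 0.50 after it. All 13 were smaller after IFN-γ, though these genes were chosen on arrays that enter the difference.

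Of 23 lists 6 passed, and of these IL-6/STAT3 targets alone passed with an estimated correlation. Those 18 genes had a median interaction of -0.31 (-0.27 on slide 1 and -0.35 on slide 2, and -0.19 without experiment 3; adjusted p = 1.14e-20, and 0.000131 with the estimate), with 0 called and 4 lower adjusted over the list alone. Immediate early genes had -0.13 (-0.12 and -0.21; adjusted p = 0.000172, adjusted p = 0.195 with an estimated correlation), and the call was lost without experiment 2 or 3 or IL-6 replicate 3 (highest adjusted p of the leave-outs 0.204). MHC class II genes had -0.23 (-0.18 and -0.31; adjusted p = 0.00344, adjusted p = 0.154 with an estimated correlation), lost without experiment 2 or 3 or untreated replicate 3 (highest adjusted p 0.199). Chemokines had -0.07 (0.04 and -0.22; adjusted p = 0.0392, or 0.0548 with the experiment as a block, adjusted p = 0.395 with an estimated correlation), and tryptophan and redox metabolism had -0.12 (-0.25 and 0.05; adjusted p = 0.0392, adjusted p = 0.195 with an estimated correlation). JAK-STAT inhibitors had a median of 0.01 and a mean of -0.18 with a test direction downward (-0.03 and 0.04; adjusted p = 0.0483, or 0.0893 with the experiment and 0.0517 with slide as a block, adjusted p = 0.538 with an estimated correlation). These 3 calls were lost without any of 10, 9 and 9 single arrays, IL-6 replicate 3 in each case, with medians from -0.13 to 0.01, from -0.21 to -0.01 and from -0.07 to 0.09.

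**Figure D3:**
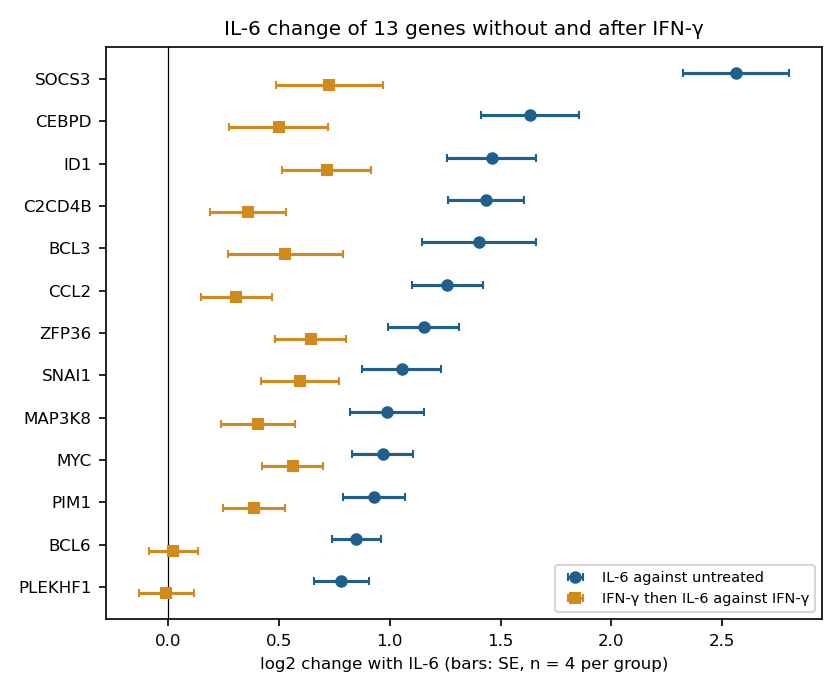
Log2 change with IL-6 of the 13 genes called for IL-6 against untreated cells, without IFN-γ (circles) and after IFN-γ (squares), with bars for the SE (n = 4 per group). All 13 lie lower after IFN-γ, SOCS3 at 0.73 against 2.56 and BCL6 at 0.02 against 0.85.

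Sets chosen on mean effects gave the same comparison. They favour neither sign of the interaction only where all groups vary equally. Over experiments, the median IL-6 change of the 12 genes below had an SD of 0.293 without IFN-γ and 0.115 after it. Choice on the mean IL-6 effect may therefore favour negative interactions, and by how much was not tested. The 12 genes higher by the mean IL-6 effect had a median IL-6 change of 1.21 without IFN-γ and 0.53 after it. Their median interaction was -0.66 (experiments -0.72, -0.91, -1.06 and -0.38; 12 of 12 genes negative), with an exact sign-flip p of 2 in 16, the smallest that 4 experiments allow. It was -1.02 without experiment 2, where the set, chosen anew, held 5 genes, and -2.17 within slide 1, where it held 1, and without experiment 3 the set was empty. The 344 genes higher by the mean IFN-γ effect had a median change with IFN-γ of 0.73 without IL-6 and 0.67 with it. IL-6 after IFN-γ moved them by a median of 0.00 (exact sign-flip p = 1), and their median interaction was -0.05, with 236 of 344 negative (exact sign-flip p of 2 in 16). The 165 genes lower by the mean IFN-γ effect had -0.01 with IL-6 after IFN-γ (exact p = 1) and a median interaction of 0.00 (exact p = 0.75).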

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

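The tests of explanations below and the counts over other splits of the arrays were chosen after the results they test were seen. Of 146 sets of 4 values examined (28 of array measures, 48 of gene levels and 70 of changes), 8 held a value far from the other 3, where chance gives 7.3 at 1 in 20. On untreated replicate 3 the median probe intensity was 71.2, against 105.5 to 111.7 on the other untreated arrays. On replicate 1 given both cytokines 5.51% of beads were left out as extreme, against 5.88% to 5.93% in its group. CXCL10 had a log2 change with IFN-γ of 4.15 in experiment 1 (others 5.11 to 5.23) and with both cytokines against untreated cells of 4.26 there (others 5.09 to 5.24). DDIT4 had -1.01 with IFN-γ in experiment 1 (others -0.85 to -0.84). SOCS3 had 1.53 with IL-6 in experiment 4 (others 2.82 to 2.97). With both cytokines against IL-6 alone, experiment 2 stood apart for GBP4 at 3.55 (others 3.90 to 3.94) and for DDIT4L at -0.53 (others -0.92 to -0.86).

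For 6 gene lists the IL-6 change differed between cells with and without IFN-γ in the test of the interaction. Their median interactions were -0.311 (IL-6/STAT3 targets), -0.229 (MHC class II), -0.13 (immediate early genes), -0.121 (tryptophan and redox metabolism), -0.066 (chemokines) and 0.007 (JAK-STAT inhibitors), and with an estimated correlation the first alone passed. Outside the genes tested, 1196 detected probes have no listed gene, and IFN-γ against untreated cells raised 21 of them and lowered 3 (limma adjusted p under 0.05). Among the bead codes without a probe, taken as background, 8 were brighter than 3 times their own median.

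The IL-6 response was smaller after IFN-γ. The tables argue against 3 technical accounts of the whole pattern: with array brightness as a covariate the STAT3 targets kept a median interaction of -0.258 (camera adjusted p = 2.86e-18, with 831 genes associated with brightness). Equal increments on the linear scale would give a ratio of 1, and the median increment after IFN-γ was 0.403 of that without it (0.256 to 0.616 over the experiments, SD 0.183, 11 of 12 genes under 1). A ceiling for genes already raised by IFN-γ would spare the others, and the 5 IL-6 genes not raised by IFN-γ alone had a median interaction of -0.545 (-0.774 to -0.324, SD 0.209), though the 7 raised had -0.953, which leaves a ceiling open as a part of the pattern. The tests on the linear scale and of a ceiling used genes chosen on the mean IL-6 effect. That choice may favour negative interactions, so these tests carry less weight. A biological difference with IFN-γ, and an effect of timing or of a change of medium before IL-6, stay open and untested.

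Another pattern was the set of 40 genes lower with IFN-γ, since the untreated and IL-6 arrays of experiments 1 and 3 lay apart on the first component. For 11 of the 40 the tables argue against those arrays as the source, because they were also among the 19 genes called lower in experiments 2 and 4 alone. For the other 29 the median change in experiments 2 and 4 was -0.449, with 29 of 29 negative, and since fewer arrays in the fit also end calls, loss of the call through fewer arrays and a part played by experiments 1 and 3 cannot be told apart. Quantile normalization as the whole source is argued against by median centring, under which the 40 genes had a median of -0.468 (40 of 40 negative). All genes had a median of 0.055 there. With quantile normalization the 40 had -0.581. The median SE of a single gene was 0.134 with median centring and 0.112 with quantile normalization. Only 14 of the 40 stayed called, with the smaller changes and wider errors. The 40 were chosen on these same arrays, so their shared sign does not bear on chance. RNA quality and a lasting biological decrease stay open and untested.

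Calls were counted over all 35 splits of the same arrays, most of which ignore the pairing. For both cytokines against untreated cells, 1 of 35 splits, the real one, gave as many genes (292, highest other split 4). Against IL-6 alone it was also 1 of 35 (246, highest other 0). For IFN-γ against untreated cells (273, highest other 1938) and IL-6 against untreated cells (13, highest other 4272), 2 of 35 did. The 1 larger split set experiments 1 and 3 against 2 and 4 for IL-6. For IFN-γ it set IFN-γ replicate 1 with untreated replicates 1, 3 and 4 against the rest. This points to a structure of the arrays along the first component. Because they mix arrays paired by experiment, these splits do not decide on chance for any of the 4 comparisons. Among the 8 splits that part every pair of an experiment, the real one was the largest in each of these 4 comparisons, with 0 as the highest other, but 8 splits are too few for a share under 0.05, so that with the pairing kept none of the 4 has such a share. With the experiment as a block 353 and 144 genes were called for IFN-γ and 27 and 0 for IL-6. For IFN-γ these held all 273 genes, and 272 of the 273 moved the same way in 4 of 4 experiments. The 273 were chosen by their p-values on these same arrays, which favours both results, so neither decides on chance. For both cytokines against IFN-γ alone (0, highest other 2; 35 of 35 splits) and for the interaction (0, highest other 2; 100 of 100 drawn) the real count of 0 left nothing for the splits to test.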

How the results depend on the processing

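Alternatives chosen after seeing the data were normexp from the probe table alone, bead values paired with probes by value, array brightness, experiments 2 and 4 only, the experiment as a block without the dimmest array, and keeping the 2 unusable probes; the planned summary of beads through a deposited identifier was not run, for want of one. Apart from the leave-outs, values of named genes kept direction and side of the threshold in 11948 of 12827 cases (0 reversed) and list tests in 755 of 817. The direction of the test was reversed for 3 lists, none of them past 0.05 there: with detection p under 0.01 on all arrays, with fewer genes, chemokines for both against IL-6 (median -0.153) and JAK-STAT inhibitors for the interaction (0.024, where the median was 0.007 against a test direction downward), and on slide 1 alone chemokines for the interaction (0.043). Medians of the interaction also differed in sign between slides for tryptophan and redox metabolism and for JAK-STAT inhibitors. Counts are higher and lower genes for IFN-γ against untreated, both against untreated and both against IL-6, and higher genes for IL-6 against untreated, set against 233 and 40, 239 and 53, 204 and 42, and 13. Median centring gave 16 and 24 lower genes in the first 2; the cause was not tested. It gave a median interaction of -0.105 for genes up by the mean IFN-γ effect, and moved that of all genes from -0.002 to -0.075. Strict detection, with fewer genes tested, gave 118 and 19, 117 and 23, and 100 and 18. With the experiment as a block (replicate block) the counts were 353 and 144, 366 and 244, 298 and 144, and 27; beside the results named in the report it changed no other call of a list or of a gene that the rule names for that comparison. With fewer arrays, slide 1 gave 64 and 2, 66 and 1, 51 and 3, and 1, slide 2 113 and 4, 125 and 6, 101 and 4, and 0, only the groups compared 11 and 14 lower genes in the first 2 and 0 for IL-6, and experiments 2 and 4 only 19, 20 and 12 lower genes and 0 for IL-6. On slide 1, with the sets chosen anew, genes up by the mean IFN-γ effect had -0.044 with both against IFN-γ, genes down 0.078 and an interaction of -0.163, and genes up by the mean IL-6 effect 0.781 and -2.174. Array weights gave 420 and 178, 447 and 206, 334 and 142, and 1 lower gene with IL-6 (S100A14, -0.58, chosen after its value was seen); the cause was not tested. The block without the dimmest array gave 362 and 111, 146 lower genes, 388 and 299, and 23; the cause was not tested. Leaving out each experiment or array gave 140 to 249 and 10 to 42, 147 to 246 and 9 to 60, 122 to 195 and 13 to 34, 2 to 13 and 0 lower for IL-6, 0 and 0 for both against IFN-γ, and 0 and 0 to 1 for the interaction. Leaving out each experiment, with the sets chosen anew, gave, for both against IFN-γ and the interaction, -0.005 to 0.028 and -0.075 to -0.037 for genes up by the mean IFN-γ effect, -0.038 to 0.019 and -0.018 to 0.011 for genes down, and 0.561 to 0.739 and -1.02 to -0.756 for genes up by the mean IL-6 effect, of which none was left without experiment 3. Signal over background limits genes near the background, whose changes are bounds or depend on the floor taken.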

Other observations

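The genes described here were chosen after their values were seen. Of the genes called with IFN-γ against untreated cells, 158 higher and 39 lower belonged to none of the fixed lists. IFI30, the lysosomal thiol reductase of antigen processing, rose by 2.63 on the log2 scale (SE 0.27, n = 4 per group, limma adjusted p = 6.12e-06), and LAP3, a leucine aminopeptidase, by 1.82 (SE 0.12). IFITM1, an antiviral membrane protein, rose by 2.00 (SE 0.37) and SAMD9L, an interferon-induced gene, by 1.86 (SE 0.18). RIPK2, the kinase downstream of NOD receptors, rose by 1.75 (SE 0.12), the ubiquitin ligase RNF19B by 1.78 (SE 0.19) and NOCT by 1.70 (SE 0.14). TMEM140, PLEKHF1, PLAAT4 and SBNO2 rose by 2.62, 2.37, 2.18 and 1.90.

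Among the lower genes outside the lists, MN1, a transcriptional coregulator, fell by 0.69 (SE 0.10, limma adjusted p = 0.000414), NOG, a secreted antagonist of bone morphogenetic proteins, by 0.68 (SE 0.17, adjusted p = 0.0374), PLEKHH3 by 0.67 (SE 0.15) and CYREN, a regulator of DNA end joining, by 0.65 (SE 0.10).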
